A study of Homo sapiens with 44 samples.

How the data were processed

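Small RNA was sequenced from 44 human corneal tissue pieces, each from the limbus (the rim where cornea meets conjunctiva and sclera, which holds the epithelial stem cells and the nearest blood vessels) or from the central cornea, which has no vessels. The donors were labelled normal, type 1 diabetic or type 2 diabetic. The labels' protocols describe donor corneas cut with a trephine into a central and a limbal part and frozen, total RNA extraction, a TruSeq Small RNA library with indexed primers, size selection on a gel and 36-base single-end reads on a GAIIx instrument. The values were deposited by the authors as RPM (reads scaled to a common library total) per mature miRNA in 1 table with 1 column per library. The submitters' processing notes name Bowtie, without a version, and the build GRCh37. Filters, mismatch settings and the denominator of the RPM are not given in the sources used here.

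The denominator holds more than miRNA reads, since the miRNA values of a library summed to 11.3% to 54.3% of the scaled total. In each column nearly all values were whole multiples of 1 smallest step, the worth of 1 read: with a tolerance of 0.02 reads, 96.0% ± 1.05 (SD, n = 44 libraries) of the values above 0 were whole. That step gave an approximate depth of 52522 to 355450 mapped reads and 17345 to 178830 miRNA reads per library. Mapped reads here means the reads in the denominator of the RPM, whatever the authors counted in it. The remaining values were fractions of a read, so the recovered reads are approximate and no count model was fitted as the main test. Counting error alone limits rare miRNAs: in 14 of 44 libraries 1 read is worth more than the filter of 10 RPM (19.0 RPM in the shallowest). PCR duplicates cannot be seen in such values.

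The table had 621 rows for 578 mature names. Of these names, 38 occurred in 2 or 3 rows with different values (81 rows), and rows of the same name were summed. Reads of near-identical family members cannot be told apart reliably in short reads. Examples are the let-7 family, miR-10a and miR-10b, miR-99a and miR-100, and miR-27a and miR-27b. How the authors assigned them is not given in the sources used here, so single members of these families are uncertain.

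The main test was fixed before the data were examined, as were the lists, the rule for named miRNAs and the first group of alternatives below. The log2(RPM + 1) values of miRNAs with at least 10 RPM in at least 6 libraries (232 miRNAs, 99.95% of the miRNA signal) were fitted with limma 3.58.1 in R 4.3.3, with 1 mean for each of 6 groups, all 44 libraries in 1 fit and an empirical Bayes trend. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method within each of 11 contrasts, and an adjusted p under 0.05 was the threshold. Adjusted p of single miRNAs are from limma except where the rank-sum test is named. A log2 difference is a difference of mean log2(RPM + 1) values. Since 1 read was worth 2.81 to 19.0 RPM, its size for rare miRNAs depends on the pseudocount. It can lie above or below the log2 ratio of the mean RPM. Errors of RPM are SD over libraries, and errors of log2 differences are SE. The diabetic contrasts weigh type 1 and type 2 equally.

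There were 21 lists of miRNAs: surface epithelium, endothelium, smooth muscle and mural cells, erythroid cells, leukocytes, skeletal muscle, neurons, the miR-183 cluster of sensory retina, pigment cells, miRNAs embedded in HOX clusters, the miR-29, let-7, miR-34 and miR-449, miR-15/16 and miR-30 families, the miR-17-92 and paralog clusters, the miR-99, miR-100 and miR-125 group, the miR-23/27/24 clusters, inflammation-responsive miRNAs, the imprinted DLK1-DIO3 cluster and the hypoxia-induced miR-210. The 18 lists with at least 2 tested members were tested with limma's camera at its preset correlation of 0.01, adjusted over lists. An estimated correlation, fry and a fit with the pairs were alternatives. Named miRNAs were, for the region and the overall diabetic contrasts, up to 10 higher and 10 lower with the largest log2 difference among those past the threshold with a mean of at least 50 RPM on a side. The other contrasts took up to 5 each way. Where fewer than 3 passed, the 3 with the smallest p are given as values. Up to 4 abundant members per list and 8 fixed miRNAs could be named whatever their test.

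The titles give each normal, type 1 and type 2 number to 1 limbal and 1 central library, 22 numbers in all. Since corneas were cut into both parts, a number was taken to mark a donor, although no label says so in words. This was decided before calls were compared. Deviations from the group means of same-numbered libraries had a median correlation across miRNAs of 0.0896 (range -0.0614 to 0.344), against -0.0139 for other numbers of the diagnosis. It was above 0.1 in 10 of 22 pairs, and 9 of 22 limbal libraries matched their own number best. The consensus correlation within numbers in limma was 0.0961. The sequencing lane was not removed from these values, and all but 2 pairs shared a lane. They therefore cannot tell a shared donor from a shared lane. The main model has no block, and the fit with the pairs is given where it changed a call.

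The column names give the sequencing lane (4 or 5). Normal libraries were split 5 and 5 in each region. Type 1 libraries lay mostly in lane 5 (5 of 6 limbal, 4 of 6 central) and type 2 libraries mostly in lane 4 (5 of 6 limbal, 4 of 6 central). The index sequences also differed between regions and between normal and diabetic libraries, so an effect of the index cannot be told apart from these groups.

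The first group of alternatives, fixed with the main test, were a pseudocount of 10 RPM, no filter, a filter of 100 RPM, quantile normalization, median-ratio scaling on 82 miRNAs seen in every library, library weights, only the groups compared, an exact rank-sum test, the pairs as a block and, for type 2 against type 1, an inferred pool as covariate. Alternatives added after seeing the data were the lane as covariate, each lane alone, voom weights on recovered reads, rows as deposited, leaving out 4 libraries under 25000 miRNA reads, a scale without miR-184, and thinning to 52522 mapped reads. The thinned libraries were first fitted with a pseudocount of 1 read and, after those calls had been seen, again with 1 RPM, the pseudocount of the main test. Both are reported with the other alternatives. For type 2 against type 1 centre, 2 central libraries whose limbal partner lay in the other lane were also exchanged or left out. In the exact rank-sum test 1 miRNA alone cannot pass: its smallest adjusted p is 0.502 with 6 against 6 libraries and 0.0579 with 6 against 10. The rank-sum test was first run with a normal approximation and then replaced by its exact form.

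The fit was tested on simulated negative binomial reads with the real means, spread and depths, in 10 simulations with 40 changed miRNAs each. For diabetic against normal limbus, with a mean of 223.1 miRNAs tested, it recovered 33.0% of 2-fold and 69.5% of 4-fold changes, and 4.65% of calls were false. For diabetic against normal central cornea (224 tested on average) it recovered 26.0% and 56.0%. For type 2 against type 1 limbus (222.3 tested on average), 14.9% of the calls were false. For the lists, a 2-fold rise of the DLK1-DIO3 list was called in 10 of 10 simulations of 18 lists, with 0 other calls. The simulated miRNAs were drawn independently of each other. In the real libraries the estimated correlation was 0.080 within the DLK1-DIO3 list and 0.45 within let-7. The simulations therefore do not bear on false list calls among correlated miRNAs.

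Library measures were compared with two-sided permutation tests in SciPy 1.17.1 (Python 3.11.15), exact below 10 libraries per side and with 100000 resamples otherwise. After the data were seen they were also compared within pairs by exact sign-flip tests, which changed a call only for depth in normal corneas. Chromosomes and host genes are from GENCODE 29. That annotation is of another build than the authors' alignment, so no coordinates are given.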

Results

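The series set out to compare miRNA levels between normal and diabetic corneas in the limbus and the central cornea. There were 10 limbal and 10 central libraries of normal corneas, and 6 of each region for type 1 and for type 2 diabetes. Depth, as mapped reads recovered from the RPM steps, was 186193 ± 83411 (SD, n = 10) in normal limbus and 120771 ± 57981 (SD, n = 10) in normal central cornea, with a difference that missed the threshold in the unpaired test (permutation test, p = 0.055, adjusted p = 0.0733 over 8 tests) and passed it within pairs (exact sign-flip test, p = 0.0254, adjusted p = 0.0406, higher in limbus in 9 of 10 pairs). Type 1 libraries had 85709 ± 28174 (limbus) and 122220 ± 45109 (centre) mapped reads, and type 2 libraries 203660 ± 80187 and 176170 ± 68849 (SD, n = 6 each). Lane 4 libraries were deeper (195840 ± 74884, SD, n = 22) than lane 5 libraries (103990 ± 34331, SD, n = 22).

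The abundance of miR-184, a miRNA highly expressed in corneal epithelium, set the regions apart. It made up 28.2% ± 6.73 (SD, n = 10) of the miRNA signal in normal limbus and 55.1% ± 12.0 (SD, n = 10) in normal central cornea (permutation test, p = 4e-05, adjusted p = 0.00016). In diabetic corneas the shares were 24.0% ± 6.00 and 57.3% ± 10.7 (SD, n = 12 each, permutation test, p = 2e-05, the smallest these resamples can give, adjusted p = 0.00016). The order held within each lane: in normal corneas the share was 24.6% in limbus and 44.8% in centre in lane 4 (exact permutation test, p = 0.00794, n = 5 each), and 31.9% and 65.5% in lane 5 (exact permutation test, p = 0.00794, n = 5 each, not adjusted). In diabetic corneas it was 21.9% and 49.1% in lane 4, and 26.1% and 65.5% in lane 5 (exact permutation test, p = 0.00216 in each, n = 6 each, not adjusted). More miRNAs were detected in limbus (244.9 ± 32.4) than in central cornea (182.9 ± 34.7) of normal donors (SD, n = 10 each, permutation test, adjusted p = 0.00203). In diabetic donors 230 ± 47.3 and 188.1 ± 40.7 were detected (SD, n = 12 each, permutation test, adjusted p = 0.048), at mean depths of 144686 and 149195 mapped reads (permutation test, adjusted p = 0.885). These depths count all mapped reads. A smaller share was left for miRNAs other than miR-184 in diabetic centre, so depth for detecting them was not matched. The miRNA share of mapped reads was 46.6% ± 2.95 in limbus and 45.7% ± 5.18 in centre of normal donors (SD, n = 10 each, permutation test, adjusted p = 0.752). In diabetic donors it was higher in limbus (48.9% ± 2.78) than in centre (41.4% ± 12.0, SD, n = 12 each, permutation test, adjusted p = 0.048), with 2 type 2 central libraries at 11.3% and 25.3%.

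In normal corneas several endothelial, mural and HOX-embedded miRNAs were far higher in limbus than in the centre. The most abundant of these was miR-10b-5p, encoded on chromosome 2 within HOXD3, at 55080 ± 19948 RPM in limbus and 1258 ± 1878 RPM in centre (SD, n = 10 each, log2 difference 6.82 ± 0.58 SE, adjusted p = 9.35e-14, higher in 10 of 10 pairs). The endothelial miR-126-5p, hosted by EGFL7 on chromosome 9, had 2820 ± 1590 and 48.1 ± 49.6 RPM (SD, n = 10 each), a log2 difference of 6.86 ± 0.59. The smooth muscle miRNA miR-143-3p, hosted by CARMN on chromosome 5, had 28060 ± 11655 and 809 ± 754 RPM (SD, n = 10 each). Its log2 difference was 5.42 ± 0.44, and that of its cluster partner miR-145-5p was 5.13 ± 0.59. All of these were higher in limbus in 10 of 10 pairs. In the other direction, miR-184 fell from 252350 ± 63704 RPM in centre to 130840 ± 28953 RPM in limbus (SD, n = 10 each, log2 difference -0.94 ± 0.24, adjusted p = 0.00294, lower in limbus in 10 of 10 pairs). With quantile normalization its difference was 0, since it ranked first in all 20 normal libraries. In diabetic limbus it ranked second in 5 of 12 libraries. With median-ratio scaling its difference was larger, -1.35 in normal and -1.56 in diabetic corneas (log2).

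**Figure D1:**
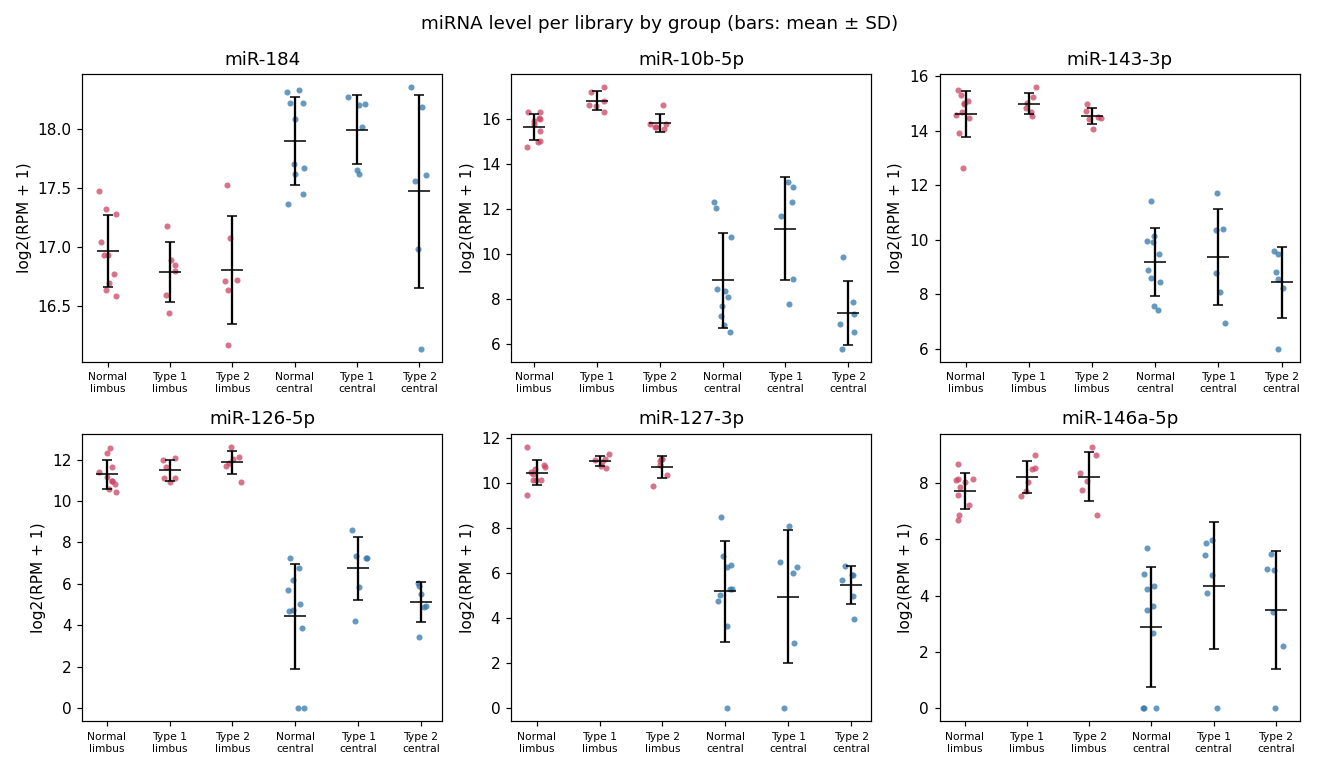
Level of 6 miRNAs as log2(RPM + 1), 1 point per library (horizontal jitter only), by diagnosis and region; bars give the mean and SD of the log2 values and the vertical axes do not start at 0. The limbal points of miR-10b-5p, miR-143-3p, miR-126-5p, miR-127-3p and miR-146a-5p lie above the central ones, and those of miR-184 lie mostly below.

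Of 232 miRNAs, 57 differed between normal limbus and centre, 54 higher and 3 lower in limbus (miR-184, miR-182-5p and miR-486-3p). The median log2 difference of all 232 was 0.59. With median-ratio scaling that median was 0.28 and the calls were 41 higher and 11 lower, and with quantile normalization it was -0.24 and they were 25 higher and 28 lower. Within lanes, 36 (lane 4) and 34 (lane 5) passed. Under the 18 alternatives the difference of miR-143-3p was 4.68 or more and that of miR-10b-5p 5.94 or more.

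By list, all 3 tested smooth muscle and mural miRNAs were higher in normal limbus, and all 3 also when adjusted over the list alone (camera adjusted p = 9.04e-06, adjusted p = 0.00264 with an estimated correlation). They are miR-143-3p and both arms of miR-145, all hosted by CARMN, so they are not independent members. Of 13 tested miRNAs of the imprinted DLK1-DIO3 cluster on chromosome 14, 11 were higher and 0 lower, 12 higher when adjusted over the list alone (camera adjusted p = 6.85e-07, adjusted p = 0.00179 with an estimated correlation). Among them miR-127-3p had 1500 ± 649 and 76.4 ± 103 RPM (SD, n = 10 each), a log2 difference of 5.26 ± 0.64. The members miR-136-3p and miR-411-5p differed by 4.48 ± 0.57 and 4.40 ± 0.61. Of 3 HOX-embedded miRNAs 2 were higher, miR-10b-5p and miR-10a-5p (3.40 ± 0.42), both also over the list alone (camera adjusted p = 0.00484, adjusted p = 0.0804 with an estimated correlation). These 2 are near-identical in sequence, so they may not be separate calls.

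Several leukocyte and inflammation-responsive miRNAs were higher in normal limbus as well. Of 4 leukocyte miRNAs 3 were higher, and 4 when adjusted over the list alone (camera adjusted p = 0.0288, adjusted p = 0.189 with an estimated correlation, adjusted p = 0.0550 in the fit with the pairs). Examples were miR-150-5p (4.27 ± 0.72) and miR-142-5p (3.28 ± 0.87, with 163 RPM in 1 central library against 35.8 in the next). For miR-155-5p, at 15.9 ± 9.63 RPM in limbus (SD, n = 10), every normal central library was listed at 0, so no size is given (adjusted p = 1.25e-06). Of 6 inflammation-responsive miRNAs 4 were higher, and 6 over the list alone (camera adjusted p = 0.0105, adjusted p = 0.189 with an estimated correlation). Among them were miR-146a-5p, a feedback inhibitor of NF-kB signalling, at 230 ± 93.6 and 14.0 ± 15.6 RPM (SD, n = 10 each, log2 4.85 ± 0.67), and miR-21-5p (1.81 ± 0.35). The 2 lists share miR-155-5p. Of 5 endothelial miRNAs only the arms of miR-126 were higher (2, and 2 over the list alone, camera adjusted p = 0.0498, adjusted p = 0.305 with an estimated correlation), while miR-221-3p differed by 0.43 ± 0.27. The erythroid miR-451a was higher (3.01 ± 0.74, adjusted p = 0.00165), at only 16.4 ± 10.7 RPM in limbus (SD, n = 10), and the erythroid list was not called (adjusted p = 0.219, 1 of 3 higher and 1 lower, or 2 lower when adjusted over the list alone).

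The epithelial list ranked low against the other miRNAs (camera adjusted p = 0.0288, adjusted p = 0.359 with an estimated correlation, adjusted p = 0.0550 in the fit with the pairs), with 1 of 12 lower, miR-184, and 0 higher, also over the list alone. Its median log2 difference was 0.30 and its mean 0.097, both above 0 although the camera direction was down, while the median of all 232 miRNAs was 0.59. The epithelial miR-205-5p had 3260 ± 1001 and 3202 ± 793 RPM (SD, n = 10 each), a log2 difference of 0.02 ± 0.23, and -0.67 with quantile normalization. Camera did not call the other lists, with adjusted p from 0.166 (miR-183 cluster) to 0.917 (miR-15/16). Of the neuron list 0 of 3 miRNAs were called and of the miR-183 cluster 1 of 3, miR-182-5p, which was lower. Higher in limbus were 3 of 4 pigment-cell miRNAs, 0 of 4 of the miR-29 family, 1 of 13 of let-7, 1 of 11 of the miR-17-92 clusters, 2 of 7 of miR-15/16, 2 of 9 of the miR-99, miR-100 and miR-125 group, 1 of 9 of miR-30 and 2 of 7 of the miR-23/27/24 clusters. Adjusted over the list alone these counts were the same except for 0 of 9 in the miR-30 family. No skeletal muscle miRNA passed the filter (0 tested), and the lone tested members of the miR-34 and miR-449 family (miR-34a-5p, 0.80 ± 0.88) and of the hypoxia list (miR-210, -0.59 ± 0.54) were not called.

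In diabetic corneas miR-10b-5p, miR-143-3p and miR-126-5p were also higher in limbus. Levels of miR-10b-5p were 89915 ± 41186 RPM in limbus and 2342 ± 3354 RPM in centre (SD, n = 12 each, log2 difference 7.05 ± 0.53, adjusted p = 8.57e-16), of miR-143-3p 28655 ± 8669 and 793 ± 906 RPM (SD, n = 12 each, 5.84 ± 0.41), and of miR-126-5p 3493 ± 1304 and 96.2 ± 105 RPM (SD, n = 12 each, 5.74 ± 0.54). Each was higher in 12 of 12 pairs. The erythroid miR-451a was not called here (1.41 ± 0.68, adjusted p = 0.102, but adjusted p = 0.0416 in the fit with the pairs), and its regional difference was not shown to differ from the normal one (interaction -1.60 ± 1.01, adjusted p = 0.947). Again miR-184 was lower, at 117250 ± 30340 against 235650 ± 82047 RPM (SD, n = 12 each, -0.94 ± 0.22, adjusted p = 0.000657, higher in limbus in 1 of 12 pairs). Of 232 miRNAs 88 differed, 84 higher and 4 lower (miR-184, miR-138-5p, miR-1260b and miR-5701, the last 2 named after their values were seen). With a median of 0.76 over all miRNAs, the split was 46 higher and 13 lower under median-ratio scaling and 29 higher and 44 lower under quantile normalization. The lower miRNA share of diabetic central libraries enters these values, since RPM are scaled to all mapped reads. Without 4 libraries under 25000 miRNA reads, which include the 2 type 2 central ones with the lowest share, 68 differed, 59 higher and 9 lower. Within lanes, 38 (lane 4) and 35 (lane 5) passed.

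By list, all 13 tested DLK1-DIO3 miRNAs were higher in diabetic limbus, also over the list alone (camera adjusted p = 1.54e-08, adjusted p = 0.000338 with an estimated correlation). Among them were miR-127-3p (5.62 ± 0.59), miR-136-3p (5.37 ± 0.52) and miR-411-5p (4.83 ± 0.55). All 3 smooth muscle and mural miRNAs were higher, also over the list alone (camera adjusted p = 0.000216, adjusted p = 0.0135 with an estimated correlation). Of the HOX-embedded ones 2 of 3 were higher, again the near-identical miR-10b-5p and miR-10a-5p, also over the list alone (camera adjusted p = 0.0194, adjusted p = 0.173 with an estimated correlation). Inflammation-responsive miRNAs were higher in 5 of 6, also over the list alone (camera adjusted p = 0.0485, adjusted p = 0.372 with an estimated correlation, adjusted p = 0.0516 in the fit with the pairs). The epithelial list again ranked low with 1 of 12 lower, also over the list alone (camera adjusted p = 0.0206, adjusted p = 0.372 with an estimated correlation, adjusted p = 0.0510 in the fit with the pairs) at a median of 0.10. So 5 lists were called, and 3 in the fit with the pairs. The endothelial list (2 of 5 higher, adjusted p = 0.132), leukocyte list (3 of 4 higher, 0.225) and miR-30 family (6 of 9 higher, 7 adjusted over the list alone, 0.388) were not called, nor were the others (adjusted p of 0.132 or more).

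Across the 232 miRNAs the regional differences in normal and diabetic libraries correlated (Pearson r = 0.837, Spearman rho = 0.685, across miRNAs, which are not independent). Both contrasts called 47 miRNAs as higher, against 19.55 for independent lists of 54 and 84, and no miRNA was called in opposite directions. Independent lists are not a full baseline here, since both contrasts were shifted upward (medians 0.59 and 0.76) and share 1 spread per miRNA. The interaction of region and diabetes, which tests whether the regional difference itself changed, gave 0 calls by limma (9 at an unadjusted p under 0.05, with 11.6 to be had by chance, 0 by the rank-sum test, smallest adjusted p = 0.947). For miR-10b-5p that difference was 0.24 ± 0.79 and for miR-126-5p -1.11 ± 0.80 (log2, adjusted p = 0.947 for both). The 3 with the smallest p were miR-25-3p (0.85 ± 0.32), miR-598 (2.38 ± 0.97) and miR-134 (1.96 ± 0.81). No list passed (0 of 18, smallest adjusted p = 0.68).

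**Figure D2:**
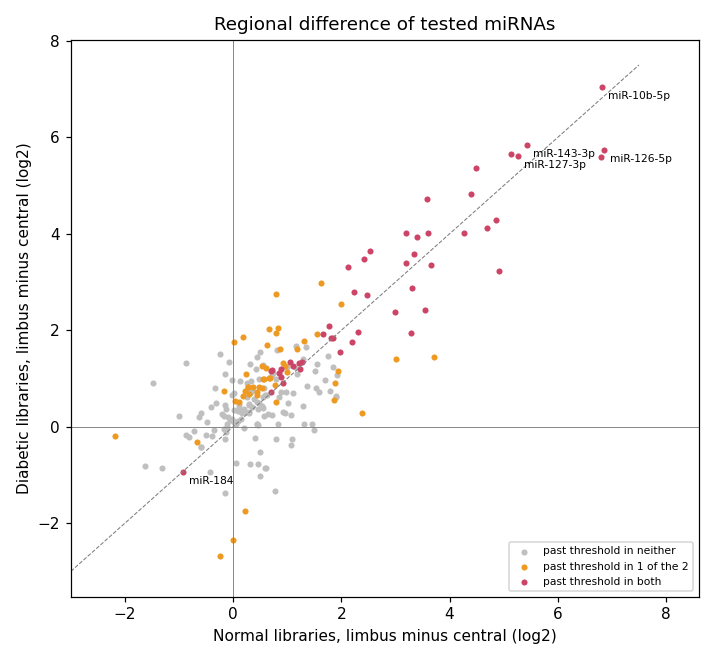
Log2 difference between limbus and central cornea of each of the 232 tested miRNAs in normal (horizontal) and diabetic (vertical) libraries; colours show whether the adjusted p passed in both, in 1 or in neither, and the dashed line marks equal differences. The 47 miRNAs called higher in both lie above 0 on both axes, with miR-10b-5p at 6.82 and 7.05, and miR-184 lies below 0 on both axes on this RPM scale (at 0 in normal corneas with quantile normalization).

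Between diabetic and normal limbus no miRNA passed the threshold. Levels of miR-10b-5p differed by 0.67 ± 0.56, of miR-143-3p by 0.14 ± 0.43, of miR-146a-5p by 0.49 ± 0.64, of miR-184 by -0.17 ± 0.23 and of miR-205-5p by 0.10 ± 0.22 (log2 ± SE, 12 diabetic and 10 normal libraries, adjusted p = 0.988 for each). No miRNA of 232 was called by limma (0, 14 at an unadjusted p under 0.05, with 11.6 to be had by chance) or by the rank-sum test (0), and voom gave 0. The 3 with the smallest p were miR-1260b (-2.62 ± 0.73, adjusted p = 0.148), miR-134 (1.96 ± 0.57, 0.148) and miR-365a-3p (-2.18 ± 0.72, 0.289), all under 30 RPM on both sides. For 61 of 78 miRNAs with a mean of at least 100 RPM, the 95% interval lay within 1 log2 unit of 0. Only 1 list was called: the DLK1-DIO3 list ranked high, with 12 of 13 members above 0, a median of 0.44, and 0 members called (1 higher over the list alone, camera adjusted p = 0.0234, adjusted p = 0.313 with an estimated correlation). By fry, which tests for a change without comparing a list with other miRNAs, its adjusted p was 0.315. The other 17 tested lists each had an adjusted p of 0.929.

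Between diabetic and normal central cornea no miRNA was called by limma (0, 12 at an unadjusted p under 0.05, with 11.6 to be had by chance), by the rank-sum test (0) or with voom (0). The 3 with the smallest p were miR-92b-3p (-0.78 ± 0.26, 204.6 ± 101 and 345 ± 152 RPM, SD, n = 12 and 10), miR-126-5p (1.502 ± 0.57) and miR-126-3p (1.58 ± 0.62), each with an adjusted p of 0.658. No list passed (0 of 18, smallest adjusted p = 0.15). Levels of miR-184 differed by -0.17 ± 0.23 and of miR-205-5p by 0.03 ± 0.22 (log2). The 95% interval lay within 1 log2 unit of 0 for 55 of 78 miRNAs with a mean of at least 100 RPM.

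Neither type of diabetes alone differed from normal at the threshold in limma: 0 calls in type 1 limbus (28 at an unadjusted p under 0.05), type 2 limbus (10), type 1 centre (12) and type 2 centre (13), with 11.6 to be had by chance. In simulations of these contrasts the fit recovered only 17.5% to 30.5% of 2-fold and 47.0% to 56.0% of 4-fold changes. The rank-sum test gave 0 in each, but cannot call 1 miRNA alone at this size. With voom type 2 limbus had 1, miR-1260b (lower, adjusted p = 0.0111), and the others 0. The smallest p in type 1 limbus belonged to miR-30c-2-3p (-2.79 ± 0.85), miR-134 (2.20 ± 0.69) and miR-654-3p (-1.92 ± 0.63), each with an adjusted p of 0.189. In type 2 limbus they belonged to miR-1260b (14.7 ± 17.5 RPM in normal limbus, SD, n = 10, and listed at 0 in type 2), miR-3065-5p (2.02 ± 0.65) and miR-409-5p (2.21 ± 0.78). In type 1 centre they belonged to miR-10b-5p (2.30 ± 0.67, adjusted p = 0.167), miR-126-5p (2.31 ± 0.69, 0.167) and miR-140-3p (-2.45 ± 0.82). In type 2 centre they belonged to miR-28-3p (-0.86 ± 0.27), miR-181a-3p (-1.73 ± 0.55) and miR-769-5p (-1.03 ± 0.33), each with an adjusted p of 0.235.

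Between the types of diabetes, miR-10b-5p was the only miRNA called in central cornea, lower in type 2. It had 4414 ± 3785 RPM in type 1 and 269.5 ± 341 RPM in type 2 central cornea (SD, n = 6 each). The log2 difference was -3.74 ± 0.75 (adjusted p = 0.00201), and 11 miRNAs had an unadjusted p under 0.05. Central values ran from 218 to 9315 RPM in type 1 and from 55.3 to 954 RPM in type 2, so the groups overlapped. The SE pools the spread of all 6 groups, and type 1 limbal values ran only from 80143 to 173311 RPM. It is thus not the SE of the 2 groups compared. With only the 12 central libraries of these types in the fit the call was lost (adjusted p = 0.625), at the same log2 difference. Over all alternatives the adjusted p ran from 4.3e-06 to 1. The rank-sum test (p = 0.0152, adjusted p = 1) cannot call 1 miRNA alone at this size. Within lanes the difference was -2.96 (lane 4, adjusted p = 0.501) and -3.21 (lane 5, adjusted p = 0.292). In limbus 0 miRNAs were called by limma and by voom (21 at an unadjusted p under 0.05), and 0 by the rank-sum test, which cannot call 1 miRNA alone at this size. The smallest p there belonged to miR-10a-5p (-1.90 ± 0.54, 5867 ± 5731 and 19473 ± 8876 RPM, SD, n = 6 each) and to miR-151a-5p and miR-6499-5p, at 8.25 ± 3.49 and 12.1 ± 10.4 RPM in type 2 (SD, n = 6) and listed at 0 in every type 1 library. Their adjusted p were 0.115, 0.115 and 0.15, and the type 1 limbal libraries were the shallower ones. Limbal miR-10a-5p also parted by lane over all diagnoses, at 2675 to 5865 RPM in 11 libraries of lane 4 and 10177 to 30566 RPM in 11 of lane 5, and within lanes its type 2 minus type 1 difference was -0.73 (lane 4) and -0.28 (lane 5, log2).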

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

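The tests of scaling to all mapped reads, of vessel and blood cell types and of limbal tissue in central pieces were chosen after the result was seen, as were those on lanes, on the scale without miR-184, on thinned libraries, on leaving out shallow libraries and on exchanging or leaving out 2 central libraries.

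Among 58 groups of libraries tested for 1 value standing apart from the rest, 9 had such a value. The bound used would give about 1 in 20 by chance for normally distributed values. RPM values are skewed, with a median of 0 for miR-126-3p and miR-142-5p in normal centre, so the chance rate here is not known. In normal limbus the miRNA share of 1 library was 39.6% (next lowest 44.6%), its miR-127-3p reached 3114 RPM in 1 library (next 1773) and miR-142-5p reached 213 RPM in 1 library (next 78.8). In normal central cornea, 1 library each reached 2725 RPM of miR-143-3p (next 1119), 50.2 RPM of miR-146a-5p (next 26.0), 63.7 RPM of miR-126-3p (next 26.0), 355 RPM of miR-127-3p (next 107) and 163 RPM of miR-142-5p (next 35.8). These 5 highest central values came from 2 libraries, with 3 in the same one. In type 2 central cornea 1 library reached 954 RPM of miR-10b-5p (next 234), and it is among the 2 libraries for which an exchange between type 1 and type 2 stays open.

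In normal corneas 54 miRNAs were called higher in limbus and 3 lower. Rescaling to reads other than miR-184 left a share of 0.902 higher and a median of 0.45 over all miRNAs. Reads other than miRNA stay in that denominator, so this removes only part of the effect of miR-184 and cannot decide on its dominance. Thinning to equal depth left a share of 0.949 (0.929 with a pseudocount of 1 read), which argues against shallower central libraries as the whole cause. It evens out mapped reads, not those left for miRNAs other than miR-184. At equal depth the calls fell from 57 to 39 (42) and the median of all miRNAs from 0.59 to 0.50 (0.20), so depth may account for part. The scaling to all mapped reads stays open: the larger of the shares under median-ratio scaling and quantile normalization was 0.788. A biological candidate, RNA of vessel and blood cell types at the limbus, also stays open, since the smallest of the 3 list medians (endothelium, mural cells, leukocytes) was 0.83 (log2), below the bound of 1 but above 0. No other split among 100 gave as many calls in normal (57, highest other 40) or diabetic corneas (88, highest other 59). Chance alone is thus unlikely as the source of these counts, though 100 splits cannot show a share below 1 in 100. The highest others exchanged libraries within pairs (free splits reached 6 and 20).

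No miRNA was called between diabetic and normal corneas, and the simulated limbal libraries bear on what that allows. The share of simulated 2-fold changes called was 0.33, so 2-fold changes may have been missed for lack of libraries or reads. For 4-fold changes the share was 0.695, which leaves that limit open. Both shares are over miRNAs of all levels, and recovery was not split by level. In this contrast the median SE was 0.29 for the 78 miRNAs with a mean of at least 100 RPM, against 0.63 over all 232 (log2). With a real count of 0 all 100 splits give as many whatever the data, so they do not show whether chance can be excluded: the highest others were 1 for diabetic against normal limbus, 20 for central cornea, 2 and 1 for type 1 and type 2 limbus, 5 and 51 for type 1 and type 2 centre, 16 for type 2 against type 1 limbus and 1 for the interaction. In centre some splits called many against a real 0 (51 and 20 at most, any call in 18 and 22 of the other splits), which points to a structure of the libraries whose source was not tested.

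Higher miR-10b-5p in type 1 than in type 2 central cornea was the only call of a single miRNA between diagnoses. Without the shallow libraries the log2 difference was -4.10 and with the lane as covariate the adjusted p was 0.00488 (4.3e-06 to 1 over all alternatives), which argue against few reads and the lane as the whole cause, and exchanging 2 central libraries between the types or leaving them out gave -4.45 and -4.91, so an exchange would not account for it. Limbal tissue in the type 1 central pieces may account for it. The excess over type 2 centre was taken as a percentage of the type 1 limbal level minus the type 2 central level. It was 3.48% for miR-10b-5p and a median of 2.86% (95% bootstrap interval -0.244 to 6.15) for 6 other miRNAs far higher in limbus. Among these were miR-126-5p at 3.83% and miR-143-3p at 2.12%, while miR-127-3p (1.81%) was higher in type 2 on the log2 scale (0.502). The 6 include miR-10a-5p (1.64%), near-identical to miR-10b-5p, and both arms of miR-126, so they are not independent. Without the type 1 central library with the highest miR-143-3p the values fell to 2.66% for miR-10b-5p and a median of 1.53% for the others. In that case miR-126-5p was at 2.28%, miR-143-3p at 0.78% and miR-127-3p at -0.089%. Normal central libraries also reached 4189 and 5166 RPM of miR-10b-5p, so such levels were not particular to type 1. The library at 5166 RPM was the highest normal central one for 4 of the 7 limbal miRNAs. Chance is not excluded either, since 24 of 100 splits of these 12 libraries called at least 1 miRNA (real 1, highest other 39, which again points to a structure of the libraries). The split by lane alone called 6 in centre and 16 in limbus, and a biological difference between the types was not tested apart from these.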

How the results depend on the processing

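Tests by lane, without shallow libraries, at equal depth, with voom, with rows as deposited, on the scale without miR-184 and with 2 central libraries exchanged or left out were chosen after the result was seen. For single named miRNAs, 4995 of 5252 values under alternatives kept their side of the threshold with no called value changing direction (332 uncalled ones changed sign), 165 lost and 68 gained a call, and 24 reversed with a call on either side. The cause of the changes below was not tested, except that the 100 RPM filter tests fewer miRNAs and each lane holds fewer libraries. Depth limits miRNAs near 10 RPM.

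Regional calls were 57 in normal and 88 in diabetic corneas. They fell to 27 and 51 with the 100 RPM filter, 36 and 38 in lane 4 alone, 34 and 35 in lane 5 alone, and in diabetic corneas 58 at equal depth. With the pairs as a replicate block they were 65 and 95. The block added miR-486-5p, miR-223-3p, let-7c and miR-21-3p in normal corneas (adjusted p = 0.0457, 0.0246, 0.0463 and 0.0352) and miR-451a, miR-29a-3p and miR-92b-3p in diabetic ones (0.0416, 0.0425 and 0.0371), ended the 4 list calls given with the results, and changed no other call of a named miRNA or list.

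The miRNAs named for small counts were chosen after their values were seen. Calls of diabetic against normal limbus, 0 in the main test, were 3 with quantile normalization (miR-134, miR-184, miR-3065-5p), 1 with library weights and 1 in lane 4 (both miR-1260b). Type 1 against normal limbus had 2 with quantile normalization and 3 with only its groups. Type 2 against normal limbus had 1 with quantile normalization, 3 with library weights, and miR-1260b as the 1 call each with lane as covariate, in lane 4 and with voom. Type 1 against normal centre had 1 with quantile normalization, 1 in lane 5 and 3 without the shallow libraries (miR-126-3p, miR-126-5p, miR-181c-5p). Type 2 against normal centre had 1 without a filter. Type 2 against type 1 limbus had 8 with library weights, 3 with only its groups, 1 at equal depth and 2 at equal depth with a pseudocount of 1 read. Type 2 against type 1 centre, 1 in the main test, had 2 without a filter, 2 at equal depth, 2 each with the 2 central libraries exchanged or left out (miR-10b-5p and miR-211-5p), and 0 with only its groups, by rank-sum and in lane 4; lane 5 called 1, miR-22-3p, in place of miR-10b-5p.

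Lists called in normal regions were 7, with 2 under an estimated correlation and 11 by fry; in diabetic regions 5, with 2, 3 with the replicate block, and 13 by fry; in diabetic against normal limbus 1, with 0 under both. With fry the direction turned up for miR-17-92 (adjusted p = 0.0463 normal, 0.000135 diabetic) and, in diabetic corneas, for the epithelial list (0.953), miR-15/16 (0.0285) and the miR-99, miR-100 and miR-125 group (0.0426).

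With quantile normalization miR-184 lost its call in normal corneas at a difference of 0, since it ranks first in all 20 normal libraries, and these log2 differences between limbus and centre turned. In normal corneas they were -0.67 for miR-205-5p, -0.65 for let-7a-5p, -0.69 for let-7b-5p, -0.14 for miR-92a-3p, -0.054 for miR-99a-5p, -0.61 for miR-27a-3p and -0.15 for miR-23b-3p. In diabetic corneas they were -0.98 for miR-205-5p, -0.97 for miR-203a, -0.57 for miR-204-5p, -0.44 for let-7a-5p, -0.43 for let-7f-5p, -0.19 for let-7c, -0.40 for let-7b-5p, -0.49 for miR-92a-3p, -0.86 for miR-100-5p, -0.40 for miR-30d-5p, -0.20 for miR-30b-5p, -0.054 for miR-27b-3p, -0.63 for miR-27a-3p, -0.52 for miR-24-3p and -0.050 for miR-23b-3p. With median-ratio scaling they were -0.53 for miR-205-5p and -0.33 for let-7f-5p in diabetic corneas.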

Other observations

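The test of exchanged central libraries was written before its result was seen, while its spread over other numbers, the fits with these libraries exchanged or left out and the comparisons of lanes were chosen after.

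Pigment-cell miRNAs were present at the limbus. In normal corneas miR-211-5p, which is hosted by a melanocyte gene, had 347 ± 140 RPM in limbus and 100.2 ± 107 RPM in centre (SD, n = 10 each; log2 difference 2.53 ± 0.68, adjusted p = 0.00363; higher in 10 of 10 pairs). In diabetic corneas it had 408 ± 160 and 90.8 ± 94.8 RPM (SD, n = 12 each; 3.64 ± 0.62, adjusted p = 5.04e-06; higher in 12 of 12 pairs). Another miRNA of the pigment-cell list, miR-508-3p, was also higher (2.99 ± 0.70 normal, 2.39 ± 0.64 diabetic), while the more abundant miR-204-5p, which shares a seed with miR-211-5p, differed by -0.21 ± 0.26 and 0.26 ± 0.23. As a list these 4 tested miRNAs were not called by camera (adjusted p = 0.585 and 0.388), and by fry, which does not compare a list with other miRNAs, they were (adjusted p = 0.000434 and 3.66e-06), 3 of 4 higher in each.

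Some members of broadly expressed families were higher in diabetic limbus than in diabetic centre on the RPM scale, while camera called neither the miR-30 list (adjusted p = 0.388) nor the let-7 list (adjusted p = 0.965). In the miR-30 family 6 of 9 were higher, such as miR-30a-5p (7527 ± 1602 and 3728 ± 1858 RPM, SD, n = 12 each; log2 1.18 ± 0.24), and in the let-7 family 4 of 13, such as let-7c (1.00 ± 0.27). Since the median of all miRNAs was 0.76 there, and 0.34 and -0.25 under median-ratio scaling and quantile normalization, the common shift makes up much of these differences. With median-ratio scaling miR-30a-5p (0.56, adjusted p = 0.0050), miR-30a-3p (0.64, 0.0232) and let-7i-5p (0.72, 0.00825) passed. Under that scaling let-7c (0.38, 0.0766) and miR-30d-5p (0.20, 0.248) did not pass. With quantile normalization the differences turned for let-7c (-0.19), miR-30d-5p (-0.40) and miR-30b-5p (-0.20). The neuron-list miR-138-5p went the other way (30.0 ± 22.7 RPM in centre and 5.43 ± 6.52 RPM in limbus, SD, n = 12 each; -2.67 ± 0.73, adjusted p = 0.0028). In normal corneas it differed by -0.24 ± 0.80. The interaction of region and diabetes called no miRNA (smallest adjusted p = 0.947), so a regional difference particular to diabetic corneas is not shown.

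The lanes differed in more than depth. With groups in the model, 36 miRNAs differed between lanes, 12 higher and 24 lower in lane 5, and 21 did after thinning to equal depth, of which 18 were shared. The smallest p belonged to miR-23c (4.25 ± 0.35 higher in lane 5) and miR-100-5p (-1.79 ± 0.17), and miR-184 was 0.65 ± 0.13 higher in lane 5 (log2). Reads of miR-100 and miR-99a cannot be told apart reliably, so the value of miR-100-5p is uncertain. These miRNAs were chosen after their values were seen.

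For 2 numbers, 1 of type 1 and 1 of type 2, the limbal and central libraries lay in different lanes. If these central libraries had been exchanged, the crossed pairs should correlate better; the mean crossed minus labelled correlation of deviations was -0.118 (labelled mean 0.0118, crossed mean -0.107). For 25 sets of other numbers of these diagnoses this difference was -0.0579 ± 0.0913 (SD, range -0.215 to 0.172). The labelled pairs show no clear match of their own, and the value passes the bound of -0.1 by less than this spread, so an exchange stays open. It bears on miR-10b-5p between the types, where exchanging these 2 libraries gave a log2 difference of -4.45 and leaving them out -4.91, against -3.74 as labelled.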
